A study of Mus musculus with 3 samples.

How the data were processed

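Single-cell RNA sequencing was carried out on lungs of C57BL/6 mouse pups at postnatal day 14. Per the labels, newborns of 6 litters were pooled and assigned at random to 3 groups: room air with saline, hyperoxia with saline, and hyperoxia with an HMGB1 peptide. Hyperoxia was 90% oxygen from postnatal day 1 to day 14, a model of bronchopulmonary dysplasia, the chronic lung disease of preterm infants. Each group was 1 library made from the lungs of 2 pups. Per the labels, the tissue was minced, digested with dispase, collagenase, elastase and DNase, treated to lyse red blood cells and sorted by flow cytometry for live cells, with a target of 6000 cells per library. Libraries were made with 10x Genomics Chromium 3′ v3.1 chemistry, in which transcripts are counted by unique molecular identifiers (UMIs), and sequenced on a NextSeq 2000. The dose, route and sequence of the peptide and the sex of the pups are not given in the sources used here.

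Per the submitters' processing notes, reads were processed with Cell Ranger on the mouse genome mm10 (GRCm38). Its version, and whether barcodes were filtered beyond cell calling, are not given in the sources used here. The authors deposited 1 table of raw UMI counts per library, with values that are whole numbers for 32245 genes. They also deposited a table of normalized signal for the 18002 barcodes of the 3 libraries together. Checked against the raw tables, each normalized value equalled the raw count divided by the cell total over the listed genes times 10000, within 0.0005. The normalized table listed 30308 genes. Of the 1937 genes absent from it, 1079 were on X, 725 on Y, 91 coded for ribosomal proteins, 13 were mitochondrial, and 29 were on other chromosomes or unmatched. The absent genes held 26.1% of all UMIs. No listed gene was matched to X or Y, and the raw counts were used throughout. Gene symbols were matched to GENCODE M21 (GRCm38), which held 31424 of the 32245 symbols, and coordinates are from that annotation.

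The room air library held 6104 barcodes and 32041234 UMIs, the hyperoxia saline library 4314 barcodes and 34519770 UMIs, and the hyperoxia peptide library 7584 barcodes and 40169682 UMIs. Cells were kept with at least 500 genes detected and under 10% of UMIs from mitochondrial genes. Barcodes of each library were scored by the share of simulated doublets among their nearest neighbours, and those with the highest scores were removed at 0.8% per 1000 barcodes, which came to 298, 149 and 460 barcodes in the order above. The kept cells numbered 5278, 3702 and 6272, with median depths of 4784.5, 6763.5 and 4433 UMIs per cell. Depth per cell was thus higher in the hyperoxia saline library than in both others.

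The 3 libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 15 neighbours was partitioned with the Leiden algorithm at resolution 1, which gave 41 clusters. Xist, Tsix, Y-linked, mitochondrial, ribosomal and haemoglobin genes, and members of the gene lists other than cell type markers, were left out of the variable genes. A cluster took the name of the class with most markers among its 10 genes of highest fold against the other clusters, with at least 3 markers and more than any other class. That naming rule was set after the clusters were seen, in place of an earlier rule on mean fold that gave names at odds with the leading genes. The classes are therefore marker-based names: "neutrophil" stands for neutrophil-like clusters, and so on, and they may differ from the study's own annotation. The clusters without a name held 2.56%, 21.6% and 14.6% of the kept cells of the room air, hyperoxia saline and peptide libraries. The pooled populations "all endothelial" and "all mesenchymal" hold the clusters, named or not, whose highest mean fold was for genes of that lineage, mesothelial cells left out. "Mononuclear phagocytes" hold the macrophage and monocyte clusters and the unnamed immune clusters nearest to them. These 3 populations were set after the data were seen.

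Counts were summed over the cells of a population and given as counts per 1000000 UMIs of that population (CPM), with exact 95% Poisson intervals. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. Hyperoxia saline was compared with room air saline, and hyperoxia peptide with hyperoxia saline, as log2 ratios with exact intervals conditional on the 2 counts. All intervals cover counting error only. They treat UMIs as independent, which fails where 1 cell holds most of a gene's UMIs. With 1 library per group no spread between animals can be estimated, so no test was run, no p-value is given and no count of changed genes is made. A value of 0 was set to a floor of 3 counts in ratios, which are then bounds.

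The choices that follow were made before the data were examined. In each contrast, genes were named in the 6 classes with the most cells in the library where they are fewest, with at least 100 cells in every library: B cells, classical monocytes, T cells, neutrophils, conventional dendritic cells, and innate lymphoid or gamma-delta T cells. The rule took the 2 genes with the highest and the 2 with the lowest ratio among genes with at least 50 CPM and 20 UMIs in the higher library and intervals that did not overlap. To leave out free RNA, the level had to reach 10% of that in the class with most of the gene. Markers of other classes and mitochondrial, ribosomal, haemoglobin, Y-linked and unnamed genes, Xist and Tsix were left out. The 2 members of a described list with the highest and the lowest ratios, Hmgb1 and Ager were also to be named. Genes named in smooth muscle, type 2 epithelial cells and the pooled populations fall outside the 6 classes. Further list members were chosen after their values were seen. For the genes taken by the rule, the cells with a UMI and the share of the UMIs in the cell with most were also counted, a step added after seeing the data.

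The 18 gene lists were inflammatory cytokines and chemokines, alternative activation and lipid-associated macrophage genes, collagen and fibrillar matrix, elastic fibre, TGF-beta response and contractile genes, p53 targets, NRF2 targets and antioxidant genes, metallothionein and acute stress, cell cycle, interferon-stimulated genes, MHC class II, surfactant and lipid synthesis, angiogenesis and endothelial signalling, hypoxia and glycolysis, nuclear genes of oxidative phosphorylation, dissociation and immediate early genes, the HMGB1 axis, and the alveolar epithelial transitional state. A member was measured with at least 20 CPM in 1 of the 2 libraries and 10 UMIs over both, and a list needed 5 measured members. A member was counted as higher or lower when the ratio reached 1.5-fold and the intervals did not overlap. A list is described by its median log2 ratio, with an interval from 500 Poisson redraws of the counts, and by its percentile among 10000 random lists matched on size and on 20 bins of expression. The percentile describes these libraries and is no test. In all, 326 medians were computed over the 11 populations.

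To ask how often genes apart under hyperoxia went the other way in the peptide library, genes at least 2-fold apart were picked with a random part of the hyperoxia saline cells and read with the other part. Each share is set beside the mean of 20 simulated peptide libraries with no difference, which hold counting error and no spread between pups. Barcodes were also divided by Xist, transcribed from the inactive X chromosome of female cells, and by the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Cells with Xist and no Y-linked UMI are called Xist-only, and those with a Y-linked UMI and no Xist are called Y-only. The contrasts were repeated in Y-only cells (hyperoxia) and Xist-only cells (peptide).

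The steps were tested on simulated counts. In mononuclear phagocytes (6033 genes for hyperoxia, 5804 for the peptide), 100% of genes set apart 1.5-fold, 2-fold or 4-fold were recovered in both contrasts. In mesenchymal cells (6875 and 6653 genes) the share was 97.0% at 1.5-fold and 100% at 2-fold and 4-fold in both. In type 2 cells (5596 and 5461 genes) it was 79.1% for hyperoxia and 94.0% for the peptide at 1.5-fold, 98.5% and 100% at 2-fold, and 100% at 4-fold. The intervals covered the true ratio for 94.5% to 95.5% of the genes in these 6 settings. The genes set apart had a mean of at least 50 CPM. The counts were drawn from the Poisson model that the intervals assume, so this cannot test clumped UMIs or a spread between pups.

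The alternatives were a loose filter on cells (200 genes, 20% mitochondrial), a strict one (1000 genes, 5%), no doublet removal, double the doublet rate (1.6%), Leiden resolutions of 0.5 and 2, all deposited barcodes, centred ratios, a mean over cells in place of summed counts, cells thinned to 1500 UMIs, no minimum CPM or 100 CPM for lists, a minimum of 1.5-fold for picked genes, and Y-only or Xist-only cells. Shares within Y-only and Xist-only cells, with and without thinning, a depth-corrected estimate of female cells with 1000 bootstrap draws, and readings with no pup in common were added after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used. Reads were not reprocessed, no cell cycle phase was called, and trajectories, splicing and cell communication were not analysed here.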

Results

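Lungs of mouse pups at postnatal day 14 were profiled cell by cell in 3 groups: room air with saline, hyperoxia (90% oxygen) with saline, and hyperoxia with an HMGB1 peptide. HMGB1 is a nuclear protein that acts as an alarm signal outside cells, and the series title names inflammation and fibrosis as what the peptide acts on. Each group was 1 library from 2 pups, so there is no replicate and the spread between animals is unknown. The room air library held 32041234 UMIs over 6104 barcodes, the hyperoxia saline library 34519770 over 4314, and the peptide library 40169682 over 7584. After filters and doublet removal 5278, 3702 and 6272 cells were kept, with medians of 4784.5, 6763.5 and 4433 UMIs. Intervals are 95% intervals and cover counting error only. Those of list medians come from redraws of the counts and those of the female estimate from bootstrap draws, and the others are exact. Where a few cells hold most UMIs of a gene, intervals are too narrow. The number of cells is given for the clearest of such genes.

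The libraries differed in the sex of their pups. Xist (X:103460366-103483254, GRCm38, GENCODE M21), a non-coding RNA of the inactive X chromosome, was found without Y-linked transcripts in 0 barcodes of the room air library, in 34.7% of the hyperoxia saline library and in 86.3% of the peptide library. Y-linked genes (Ddx3y, Y:1260771-1286629, Uty, Y:1096861-1245759, Kdm5d, Y:897788-956786, and Eif2s3y, Y:1010543-1028847) were found without Xist in 64.0%, 42.1% and 0%. Both kinds appeared together in 1.62% of the barcodes of the hyperoxia saline library, in 6 barcodes of the room air library and in 1 of the peptide library. Room air therefore held male cells, the peptide library female cells, and hyperoxia saline both, so Y-only values are given beside part of the values for hyperoxia against room air, and Xist-only values beside most of those for peptide against saline.

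**Figure D1:**
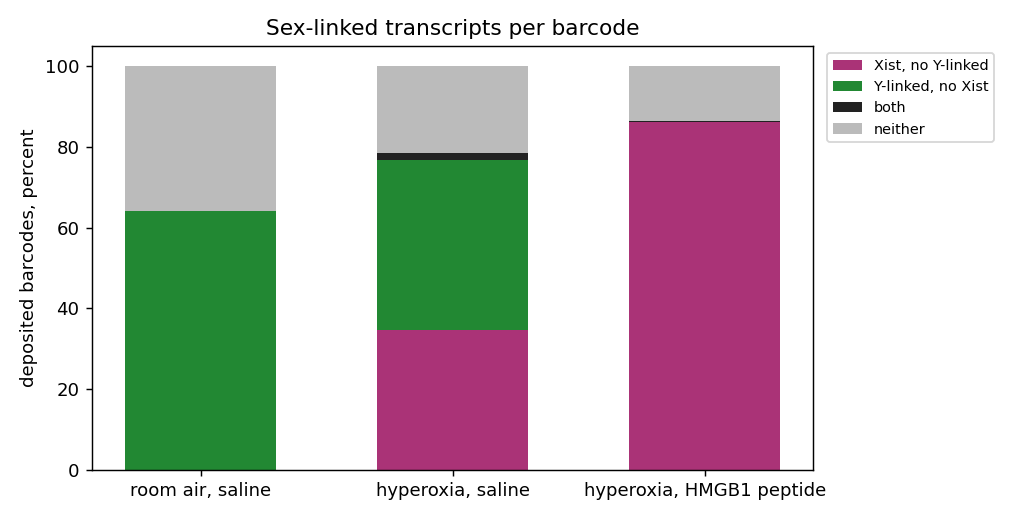
Stacked bars give the percent of deposited barcodes in each library with Xist alone, Y-linked transcripts alone, both or neither. Xist alone stood at 34.7% in hyperoxia saline and 86.3% in the peptide library.

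The comparison of hyperoxia saline with room air saline asks what the oxygen exposure did to the cells of the lung. Neutrophils, first responders to injury, made up 3.79% (3.29% to 4.34%) of the room air cells and 17.9% (16.7% to 19.2%) of the hyperoxia cells, 4.72-fold higher. Alveolar macrophages, which clear surfactant, were 30.4-fold lower, with 390 cells against 9. The cluster named general capillary endothelial was 60.7-fold lower, with 346 cells against 4. Most hyperoxia endothelial cells were in unnamed cluster 17, whose nearest marker set by mean fold was also general capillary. Its leading gene, Apln, is in the marker set of another class, aerocyte (Car4) capillary cells. Myofibroblasts, which lay down elastin as alveoli form, were 226 cells in room air and 0 under hyperoxia, which at the floor of 3 cells allows a share of up to 0.0810% and is at least 52.8-fold lower. In Y-only cells the log2 ratio was 2.52 (2.17 to 2.88) for neutrophils and -5.59 (-7.88 to -4.03) for alveolar macrophages. Y-only cells leave out the female cells of the hyperoxia saline library. Neutrophils were 2.36% of its Xist-only cells, 15.5% of its Y-only cells and 2.71% of room air Y-only cells. Xist is missed in many neutrophils, and an estimate corrected for detection put them at 8.25% (5.52% to 11.9%) of the female cells. Alveolar macrophages were 0.49% of the Xist-only cells. Shares depend on enzyme digestion and the sort for live cells, and depth per cell was highest under hyperoxia saline.

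**Figure D2:**
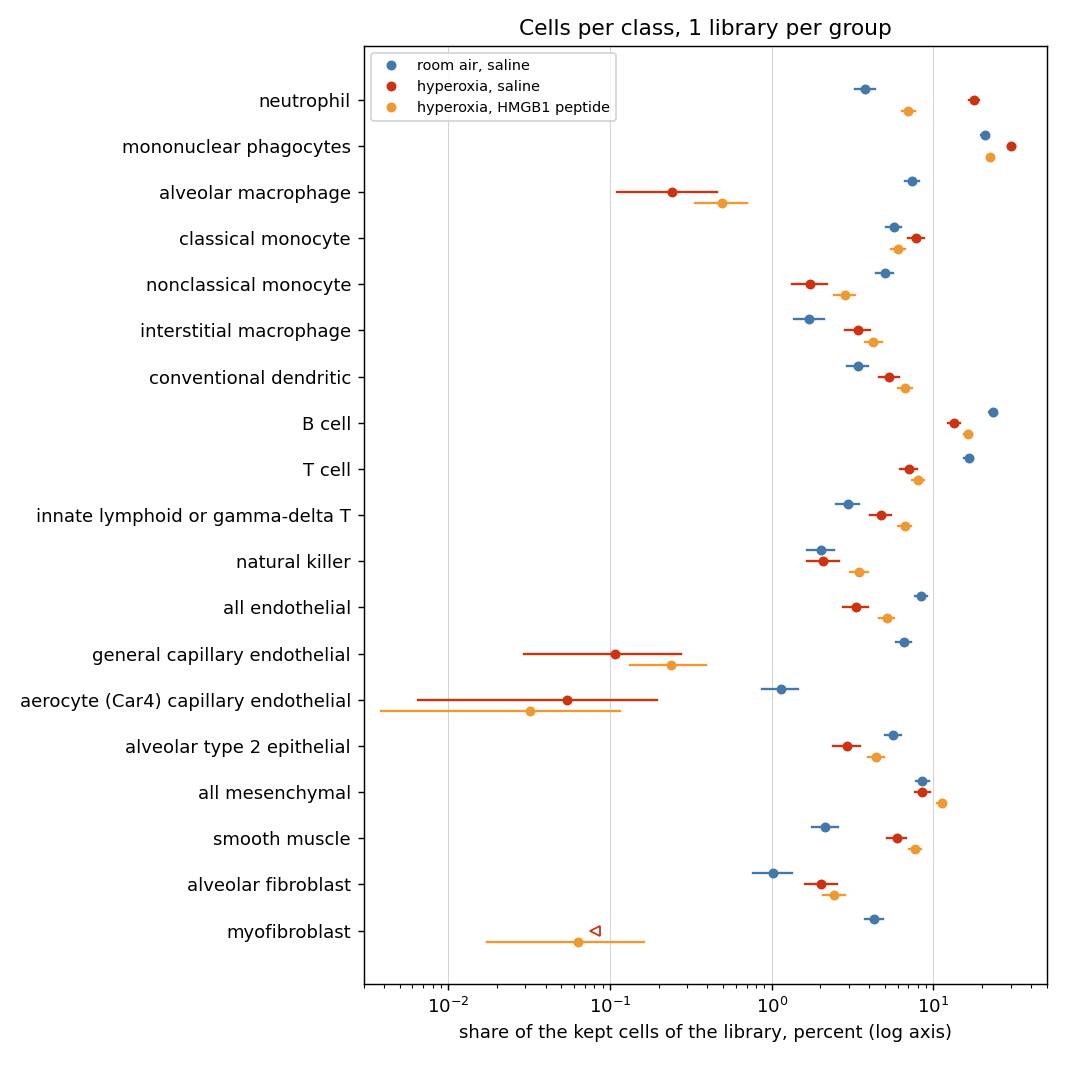
Points give the share of kept cells per class, in percent on a log axis, for the 3 libraries, with exact 95% intervals; an open triangle marks the limit of 3 cells where a class had 0 cells. Neutrophils stood at 3.79% in room air, 17.9% in hyperoxia saline and 7.00% with the peptide.

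Neutrophils fell into 2 clusters: cluster 4 held all 200 room air neutrophils and 360 of those under hyperoxia, and cluster 14 held 0 and 302. With no doublet removal the log2 ratio of the neutrophil share was 1.39, and with the loose filter on cells it was 1.47; in both settings the counterpart of cluster 14 met the rule for no name. Mononuclear phagocytes together were 20.7% of room air and 30.4% of hyperoxia cells, a log2 ratio of 0.55 (0.43 to 0.67), and 0.79 in Y-only cells. They were 22.5% of the Xist-only and 40.6% of the Y-only hyperoxia saline cells, against 23.4% of room air Y-only cells. Classical monocytes were higher at 0.46 (0.22 to 0.70) and interstitial macrophages at 1.00 (0.60 to 1.40), while nonclassical monocytes were lower at -1.53 (-1.94 to -1.13). Unnamed phagocyte clusters were a large part of the hyperoxia library: cluster 8, led by Spp1, Arg1, Ccl2 and Gpnmb, held 2 room air and 325 hyperoxia cells, and cluster 5, led by Retnla, Mmp12 and Ccl24, held 48 and 309. A cluster that sits mostly in 1 library may be that library and not a cell type. B cells were lower at -0.79 (-0.94 to -0.64), T cells at -1.23 (-1.43 to -1.03) and alveolar type 2 cells, which make surfactant, at -0.94 (-1.27 to -0.62). Shares are relative, so higher shares of neutrophils and phagocytes lower those of all other classes. B cells were 21.9% of Xist-only and 7.87% of Y-only hyperoxia saline cells, against 19.4% of room air Y-only cells. In the same order T cells were 8.22%, 6.08% and 16.3%, and type 2 cells 4.96%, 2.46% and 6.30%.

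All endothelial cells together were 8.39% of room air cells and 3.32% of hyperoxia cells, 2.53-fold lower. Cluster 18 held 78.1% of the room air endothelial cells and 3.25% of those under hyperoxia, where unnamed cluster 17, led by Apln, Angpt2 and Inhba, held 84.6% against 2.26% in room air. Mesenchymal cells as a whole stood at 8.54% in both libraries. Among them cluster 24, named myofibroblast, held 50.1% in room air and 0 under hyperoxia, and smooth muscle cells (clusters 11 and 19) were 2.14% and 5.92% of all cells, 2.76-fold higher.

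In mononuclear phagocytes 22 of 24 measured inflammatory cytokine and chemokine genes were higher under hyperoxia, 1 was lower and 1 neither. The list median was 1.71 (1.67 to 1.77) and 1.83 in Y-only cells, against a median of -0.16 over all measured genes of these cells. The hyperoxia saline phagocytes held 660 Y-only and 277 Xist-only cells, which differed. Over 270 genes at least 2-fold higher under hyperoxia in Y-only cells, the median log2 ratio of Xist-only to Y-only cells was -0.70. The size of the pooled values thus rests in part on the Y-only cells. Il1b, a cytokine made by activated macrophages, stood at 474 and 3008 counts per 1000000 UMIs (CPM), Tnf at 25.8 and 208, and the monocyte attractant Ccl2 at 96.7 and 2212. Il18 was the other way, at 202 and 36.9 CPM. Saa3 (7:46711998-46715700), an acute phase protein, had 1 UMI in room air and 284 CPM under hyperoxia, a log2 ratio of 10.95 (8.47 to 16.26). Of 17 alternative activation and lipid-associated genes 9 were higher and 5 lower, with Arg1 at 2.86 and 2351 CPM and Spp1 at 116 and 6112 CPM, and Retnla lower at 524 and 38.6 CPM. Inflammatory and other values of the pooled phagocytes move with the mix of clusters: of these cells, alveolar macrophages (cluster 12) were 35.7% in room air and 0.80% under hyperoxia, cluster 5 was 4.40% and 27.5%, and cluster 8, led by Spp1 and Arg1, 0.18% and 28.9%. Cidec, a lipid droplet gene of alveolar macrophages, was lower at 664 UMIs and 1 UMI, with a log2 ratio of -10.10 (-15.41 to -7.62), and so was Acaa1b at -9.73 (-15.04 to -7.25). Hypoxia and glycolysis genes were higher in 17 of 21 cases and lower in 0, among them the glucose transporter Slc2a1 (11.9 and 107 CPM). Of 13 cell cycle genes 0 were higher and 9 lower, with a median of -0.74 (-0.86 to -0.64). The immune clusters named cycling, 113 cells in room air and 45 under hyperoxia, are not counted among the phagocytes. That median therefore leaves out any dividing phagocytes in them and is no measure of phagocyte division.

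In classical monocytes, a single cluster, 9 of 19 inflammatory genes were higher, 2 lower and 8 neither, with a median of 0.57 (0.34 to 0.70), and 0.74 in Y-only cells. Saa3 and Lrg1 had 0 UMIs in room air and 552 and 232 CPM under hyperoxia, at least 335-fold and at least 141-fold higher. The hyperoxia saline monocytes held 166 Y-only and 85 Xist-only cells, which differed. Over 169 genes at least 2-fold higher under hyperoxia in Y-only cells, the median log2 ratio of Xist-only to Y-only cells was -0.76. The size of the pooled monocyte values thus rests in part on the Y-only cells. Retnla was 82.3 CPM and 0, at least 67.1-fold lower, but 148 of its 150 room air UMIs were in 1 cell, and with the strict filter on cells its log2 ratio was 0.63. Interferon-stimulated genes were lower in 14 of 20 cases and higher in 0, with a median of -0.97 (-1.27 to -0.85) and -1.32 in Y-only cells. Oasl2 stood at 88.9 and 16.0 CPM, and Ifit2 was lower at -4.33. In neutrophils 11 of 17 inflammatory genes were higher and 1 lower, with a median of 1.26 (1.05 to 1.36) and 1.70 in Y-only cells. Ccl3, a chemokine, stood at 22.9 and 700.4 CPM. That median was -0.10 with no doublet removal and -0.16 with the loose filter on cells. The neutrophil genes at the ends of the range were Wfdc17 (63.6 and 3268 CPM) and Igfbp6 (3 UMIs in room air, 5.08, 3.52 to 7.36) on the higher side, and Rsad2 (96.6 and 13.8 CPM) and Cebpe (91.5 and 15.8 CPM), a factor of granulocyte maturation, on the lower side. Neutrophil interferon-stimulated genes were lower in 5 of 15 cases and higher in 0, with a median of -0.74 (-0.96 to -0.37) over all cells. There the median over all measured genes was -0.16 and 95% of random lists of that size lay between -0.61 and 0.20. In Y-only cells, with no random lists, the interferon median was -0.47.

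Targets of p53, the factor that answers DNA damage, were higher across the structural cells. In endothelial cells 17 of 22 were higher and 1 lower, with a median of 1.51 (1.38 to 1.81), and 1.36 in Y-only cells, and Cdkn1a, a cell cycle inhibitor, stood at 111.4 and 1378 CPM. Gdf15, a stress cytokine, had 0 UMIs in room air and 500.4 CPM under hyperoxia, at least 311-fold higher. In type 2 cells 11 of 19 were higher and 1 lower, with Cdkn1a at 36.5 and 534 CPM and Bax at 34.0 and 188 CPM. Phlda3 was 1.42 and 76.3 CPM, a log2 ratio of 5.75 (4.37 to 7.64), and Gdf15 had 3 UMIs in room air, with 5.63 (4.04 to 7.93). In mesenchymal cells 13 of 19 were higher and 1 lower, at a median of 1.37 (1.17 to 1.67), and in smooth muscle 12 of 19 and 1, at 1.298 (1.08 to 1.71). In Y-only cells the medians were 1.45 in type 2 cells and 1.42 in both mesenchymal cells and smooth muscle. Targets of NRF2, the factor that answers oxidants, were higher in 14 of 20 cases in endothelial cells and in 16 of 21 in type 2 cells, with 1 lower in each, and Y-only medians were 1.44 and 1.22. Hmox1, which breaks down haem, stood at 9.10 and 183 CPM in endothelial cells, and Gpx2 at 2.13 and 52.5 CPM in type 2 cells.

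In type 2 cells 10 of 11 genes of the alveolar epithelial transitional state, a state seen between type 2 and type 1 cells after injury, were higher and 0 lower. Their median was 1.49 (1.36 to 2.03), and 2.26 in Y-only cells, with Krt8 at 137 and 383 CPM and Lgals3 at 13.8 and 215 CPM. Surfactant and lipid synthesis genes were lower in 10 of 23 cases and higher in 0, with a median of -0.46 (-0.51 to -0.42), and -0.60 in Y-only cells. Abca3, the lamellar body lipid pump, stood at 1105 and 533 CPM, Acoxl at 251 and 24.2 CPM, and Sftpc, a surfactant protein gene, at 203994 and 151236 CPM. Rian, a non-coding RNA, was lower at -3.04 (-3.91 to -2.28). Nuclear genes of oxidative phosphorylation were higher in 28 of 35 cases and lower in 0, with a median of 0.84 (0.78 to 0.94). Free RNA from type 2 cells was present in all libraries: Sftpc in B cells stood at 222, 98.3 and 207 CPM in room air, hyperoxia saline and peptide, or 0.109%, 0.065% and 0.114% of the type 2 level.

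Of 23 angiogenesis and endothelial signalling genes 5 were higher and 10 lower in endothelial cells, with a median of -0.22 (-0.44 to -0.09), and -0.53 in Y-only cells. Angpt2, an antagonist of the Tek receptor, stood at 13.4 and 407 CPM, Tek itself at 558 and 125 CPM and the apelin receptor Aplnr at 411 and 46.1 CPM. Wif1, an inhibitor of WNT signalling, had 135 UMIs in room air and 0 under hyperoxia, at least 33.5-fold lower, and Cadm1 stood at 243 and 9.36 CPM. AA467197 was higher with 1 UMI in room air and 251 under hyperoxia, a log2 ratio of 8.40 (5.91 to 13.71). These values move with the exchange of cluster 18 for cluster 17.

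The series title names fibrosis. Collagen genes were not higher as a group in the pooled mesenchymal cells, whose mix of clusters differed between the libraries. Of 25 collagen and fibrillar matrix genes 5 were higher, 7 lower and 13 neither, with a median of 0.02 (-0.20 to 0.15), and -0.0026 in Y-only cells. Col1a1 stood at 11621 and 5464 CPM and Col3a1 at 15675 and 5771 CPM, and Timp1, an inhibitor of matrix proteases, at 34.3 and 399 CPM. In smooth muscle, where the same 25 genes were measured, 11 were higher and 0 lower, with a median of 0.58 (0.52 to 0.70), and 0.60 in Y-only cells, and Col12a1 at 81.1 and 532 CPM. Cluster 19, led by Col12a1, Postn and Tnc, was 28 of the 113 smooth muscle cells in room air and 103 of the 219 under hyperoxia, so these values move with its share. Elastic fibre genes were higher in 2 and lower in 7 of 17 cases in mesenchymal cells, with a median of -0.31 (-0.41 to -0.23), and -0.26 in Y-only cells, and Eln at 26105 and 16353 CPM. TGF-beta response and contractile genes were higher in 12 of 20 cases and lower in 1, with a median of 0.73 (0.64 to 0.83), and 0.78 in Y-only cells, and Acta2 at 2708 and 6752 CPM. The stress list with the metallothioneins was higher in 6 of 9 cases and lower in 1. Mt2 (8:94172664-94173568), a metal-binding protein, stood at 18.0 and 528 CPM. Saa3 (3 UMIs in room air and 29 cells under hyperoxia, 7.14, 5.58 to 9.42) and haptoglobin (Hp, 6.03, 5.04 to 7.24) had the highest ratios in mesenchymal cells and Cyp2e1 (-4.55, -5.38 to -3.83) and Vsnl1 (-3.71, -4.38 to -3.10) the lowest. In smooth muscle these were Ccnd1 (2 UMIs in room air, 5.99, 4.13 to 9.04), Fst (4.90, 3.85 to 6.22), Megf6 (-3.84, -4.81 to -2.97) and the muscarinic receptor Chrm2 (-3.76, -4.29 to -3.27). The mix of mesenchymal clusters differed, with cluster 24 nearly all from room air. Smooth muscle was 113 of 451 mesenchymal cells in room air and 219 of 316 under hyperoxia. Acta2, a smooth muscle marker, and the TGF-beta response and contractile median of mesenchymal cells therefore move with that share. Adventitial fibroblasts (cluster 27), with Col1a1 and Col3a1 among their leading genes, were 12.9% of mesenchymal cells in room air and 6.96% under hyperoxia. The collagen and elastic fibre values of pooled mesenchymal cells move with the mix too, so they do not settle whether matrix genes differ within a cell class.

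Some of the lowest ratios in lymphoid and dendritic cells came from single cells. In B cells Igha, the IgA heavy chain, had 462 UMIs in room air and 3 under hyperoxia, a log2 ratio of -6.12 (-8.40 to -4.56), with 457 of the 462 in 1 cell. Dynll1 was lower at -1.36 (-1.61 to -1.12). Ppp1r21 was higher at 1.52 (1.23 to 1.81) and Vpreb1, part of the surrogate light chain of precursor B cells, at 1.22 (0.81 to 1.63), with UMIs in 7 room air and 5 hyperoxia cells; in Y-only cells Vpreb1 was at most -2.41. In T cells Elovl6 was higher at 2.29 (1.85 to 2.74) and Socs3 at 2.00 (1.65 to 2.35), and Dapl1 and Cd69 were both lower at -1.19. In dendritic cells the cyclin gene Ccnd2 stood at 27.3 and 264 CPM and Ndrg1 at 8.59 and 56.0 CPM, while Ccl24 (3 UMIs under hyperoxia, -6.15, -8.45 to -4.58) and Retnla (-6.08, -7.30 to -5.09) were lower. All 137 room air UMIs of Ccl24 were in 1 dendritic cell, and those of Retnla were in 15. In innate lymphoid or gamma-delta T cells Pdcd1, an inhibitory receptor, was higher at 2.27 (1.53 to 3.09) and Ddit4 at 1.99 (1.28 to 2.78), with Cmah at -3.04 (-4.25 to -2.01) and Klra1 at -2.81 (-3.68 to -2.02), from 7 and 5 hyperoxia cells. With the strict filter on cells Cmah was at 2.73.

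Hmgb1 itself (5:149046702-149184489) was lower in endothelial cells, at 749.8 and 463 CPM, and close in phagocytes, at 289 and 334 CPM, and in type 2 cells, at 423 and 492 CPM. Ager (17:34597862-34600936), which codes for the HMGB1 receptor RAGE and marks type 1 cells, stood at 1299.9 and 527 CPM in type 2 cells. The HMGB1 axis list was lower in 6 of 8 cases in endothelial cells and higher in 1, with a median of -0.79, and in phagocytes 3 of 10 were higher and 1 lower.

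The comparison of hyperoxia peptide with hyperoxia saline asks what the peptide did under oxygen. Neutrophils were 7.00% (6.38% to 7.66%) of the peptide cells against 17.9%, 2.55-fold lower, and the peptide library also had lower levels of inflammatory genes in its phagocytes. The peptide cells were female and the saline cells of both sexes. In Xist-only cells the log2 ratio of the neutrophil share was -0.39 (-1.005 to 0.26) in place of -1.35 (-1.53 to -1.18), from 98 of the peptide neutrophils and 29 of the saline ones. Neutrophils carry few UMIs, a median of 1338 with the peptide and 2115.5 with saline, and Xist alone was found in 22.3% of those in the peptide library and in 4.38% of those in the hyperoxia saline library, where Y-linked transcripts alone were found in 38.1%.

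Mononuclear phagocytes were 22.4% of the peptide cells against 30.4%, a log2 ratio of -0.44 (-0.55 to -0.32), and 0.07 (-0.12 to 0.26) in Xist-only cells. Cluster 8 held 186 peptide cells against 325 and in Xist-only cells its share had a log2 ratio of 0.12 (-0.40 to 0.68). Alveolar macrophages (31 cells against 9), general capillary cells (15 against 4) and myofibroblasts (4 against 0) stayed far below their numbers in room air. All endothelial cells were 5.15% against 3.32%, a ratio of 0.63 (0.33 to 0.94), and 0.41 (-0.02 to 0.86) in Xist-only cells, and cluster 17 held 78.0% of them. Type 2 cells were higher at 0.60 (0.28 to 0.94), and at -0.04 (-0.44 to 0.39) in Xist-only cells. B cells were higher at 0.28 (0.12 to 0.44) and lower in Xist-only cells, at -0.46 (-0.66 to -0.26). The cycling clusters 23 and 30 together were higher at 1.32 (0.84 to 1.82) and at 0.71 (0.11 to 1.36) in Xist-only cells. Cluster 30, led by the precursor B cell genes Igll1 and Vpreb1, held 10 saline and 85 peptide cells, and cluster 23 held 35 and 105.

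In mononuclear phagocytes 11 of 24 inflammatory genes were lower in the peptide library, 0 were higher and 13 neither. The median was -0.54 (-0.61 to -0.50) over all cells and 0.12 over Xist-only cells. Il1b stood at 3008 CPM with saline and 1564 with the peptide, at -0.94 over all cells and -0.24 in Xist-only cells. Ccl2 was at -1.57 and -0.30 and Cxcl2, a neutrophil attractant, at -1.23 and -0.05. Saa3 was lower at -3.02 (-3.19 to -2.85) over all cells and higher at 2.05 in Xist-only cells, but 49 of 1405 peptide phagocytes held its 309 UMIs, with 89 in 1 cell. Arg1 was at -2.82 and -0.58, Spp1 at -2.50 and 0.06, and Csta2, an inhibitor of cysteine proteases, at -3.19 and -1.05. The mix of phagocyte clusters differed here too: of 1124 phagocytes with saline and 1405 with the peptide, cluster 8 held 325 and 186, interstitial macrophages were 126 and 267, and nonclassical monocytes 64 and 177. Hypoxia and glycolysis genes were lower in 16 of 21 cases, with a median of -0.75 (-0.84 to -0.70), and -0.10 in Xist-only cells. MHC class II genes, which present antigen, had a median of 0.42 (0.37 to 0.46) with 7 of 7 neither higher nor lower, and -0.11 in Xist-only cells. Prg4 (3.44 and 7.60) and the scavenger receptor Marco (2.68 and 1.13), both higher, are with Saa3 among the leading genes of the small cluster 39, which held 3 saline and 16 peptide cells; Prg4 was found in 6 saline and 19 peptide phagocytes.

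**Figure D3:**
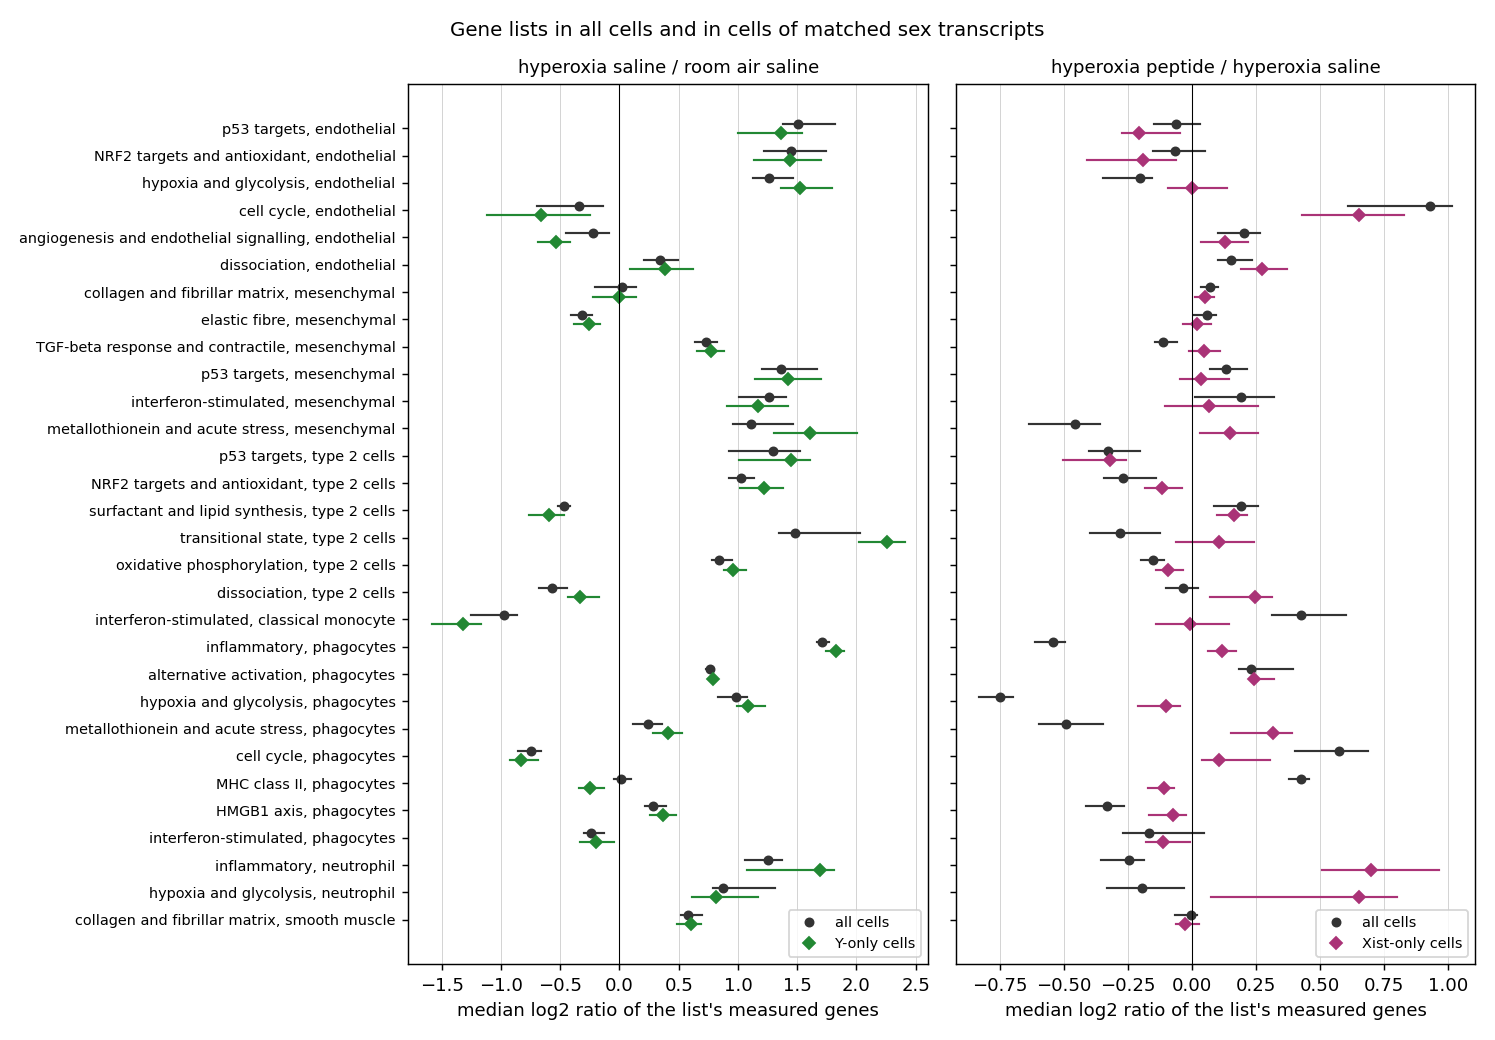
Points give the median log2 ratio of gene lists per population, for all cells and for Y-only (hyperoxia) or Xist-only (peptide) cells, with 95% intervals from 500 redraws of the counts. The inflammatory list of phagocytes stood at 1.71 under hyperoxia in all cells, and for the peptide at -0.54 in all cells and 0.12 in Xist-only cells.

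In classical monocytes 4 of 18 inflammatory genes were lower with the peptide and 1 higher, with a median of -0.31 (-0.47 to -0.16), and 0.04 in Xist-only cells. Saa3 was 37.0-fold lower with the peptide, at -5.21 (-5.83 to -4.65), and Lrg1 16.8-fold lower, at -4.07 (-4.73 to -3.48). In Xist-only cells these were -0.93 and -0.90. Interferon-stimulated genes were higher in 7 of 17 cases, with a median of 0.43 (0.31 to 0.61), and -0.01 in Xist-only cells. Amz1 (1.11, 0.66 to 1.57) and Itpr1 (1.10, 0.71 to 1.504) had the highest ratios there, with 0.25 and 0.41 in Xist-only cells. In neutrophils 2 of 18 inflammatory genes were higher, 4 lower and 12 neither, with a median of -0.25, 0.70 in Xist-only cells and 0.20 with the loose filter on cells. Cluster 14 was 45.6% of the saline and 27.3% of the peptide neutrophils, so these values move with its share. Wfdc17 stood at 3268 and 389 CPM (-3.07, and -1.62 in Xist-only cells) and Prnp at -3.06 and -1.83. Gstm1 (3.36, 2.23 to 4.67), a glutathione transferase, and Gpnmb (3.26, 2.76 to 3.79) were higher, at 3.76 and 2.44 in Xist-only cells. Gstm1 was found in 5 of 662 saline and 12 of 439 peptide neutrophils and Gpnmb in 8 and 23, and Gstm1 was at -0.46 with no doublet removal. Collagen genes had a median of 1.81 in the same neutrophils, with 4 of 8 higher, and Gpnmb leads phagocyte cluster 8, so RNA carried over from other cells is not excluded.

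Matrix genes of mesenchymal cells were close in both hyperoxia libraries. Of 25 collagen and fibrillar matrix genes 1 was higher, 2 were lower and 22 neither, with a median of 0.07 (0.03 to 0.10) and 0.05 in Xist-only cells. Col1a1 stood at 5464 CPM with saline and 5987 with the peptide, and Col3a1 at 5771 and 6830 CPM. Timp1 was lower at -1.23, and at -0.10 in Xist-only cells. Of 17 elastic fibre genes 0 were higher or lower (median 0.06, -0.01 to 0.09), and of 20 TGF-beta response and contractile genes 1 was lower, with a median of -0.11 (-0.14 to -0.06), and 0.05 in Xist-only cells. Mt2 was lower at -2.09 (-2.22 to -1.96) in mesenchymal cells and -2.14 (-2.30 to -1.98) in smooth muscle, and at 0.11 and 0.03 in Xist-only cells. Ereg, a ligand of the EGF receptor, was at -1.87 and -0.29. Dbp (0.98, 0.69 to 1.28), a circadian factor, and Itm2a (0.83, 0.61 to 1.06) were higher in mesenchymal cells, at 0.55 and 1.11 in Xist-only cells. In smooth muscle Pdzd2 (1.13 and 1.36) and Isg15 (0.95 and 3.72) were higher and Sfrp1 (-1.79 and -1.05) lower, the Xist-only value given second.

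In type 2 cells the stress and transitional lists that were higher under hyperoxia had medians below 0 with the peptide, with most of their genes neither higher nor lower. The p53 targets had a median of -0.33 (-0.40 to -0.19), with 2 of 18 lower and 0 higher, and -0.32 in Xist-only cells. The NRF2 targets were at -0.27 (-0.35 to -0.15), with 2 of 21 lower, and -0.12 in Xist-only cells. The transitional state was at -0.28 (-0.41 to -0.11), and 0.11 in Xist-only cells. Surfactant genes were at 0.19 (0.08 to 0.26), with 23 of 23 neither higher nor lower, and 0.16 in Xist-only cells. With the strict filter on cells, which left 27 saline and 86 peptide type 2 cells, the p53 targets were at -0.20, the NRF2 targets at 0.36, the transitional state at 0.72 and the surfactant genes at -0.16. Lyz1 (10:117287797-117292868), a lysozyme of type 2 cells, stood at 2207 CPM in room air, 339 with saline and 938 with the peptide, 1.47 (1.35 to 1.59) against saline, 1.51 in Xist-only cells and 0.36 with the strict filter. It was found in 90 of 296, 23 of 108 and 81 of 278 type 2 cells, in the same order. Thbs3 was higher at 1.04 and 1.15, Cxcl17 lower at -1.58 and -1.21, and Tnfrsf12a at -1.03 and -0.12. Ager was at 0.38, and 0.75 in Xist-only cells.

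In endothelial cells 12 of 24 cell cycle genes were higher with the peptide and 0 lower, with a median of 0.93 (0.66 to 1.02) and 0.65 in Xist-only cells. Top2a, an enzyme of dividing cells, stood at 51.4 CPM in room air, 7.92 with saline and 80.7 with the peptide. The histone gene Hist1h1b was higher at 3.66 (2.58 to 5.00), and 3.81 in Xist-only cells. It was found in 5 of 123 saline and 16 of 323 peptide cells, with 34 of its 144 peptide UMIs in 1 cell. Its ratio thus rests on UMIs in few cells and does not show that more cells held it. Esm1, a gene of sprouting vessels, stood at 45.4 and 122 CPM (1.43, and 1.37 in Xist-only cells), from 8 of 123 saline and 27 of 323 peptide cells. The lymphatic genes Ccl21a (192 UMIs and 1) and Mmrn1 (330 UMIs and 2) were lower, at -8.28 (-13.59 to -5.79) and -8.06 (-11.12 to -6.20), but each was found in 6 saline cells, and Ccl21a was at 1.83 with no doublet removal. In B cells Hist1h1b (1.40, 0.85 to 1.97) and Col5a3 (1.27, 0.76 to 1.82) were higher and Lamb3 (-0.97, -1.42 to -0.53) and Cd200 (-0.88, -1.29 to -0.47) lower. In Xist-only cells these were 1.013, 1.02, -0.84 and -0.70. With the strict filter on cells Col5a3 was at -1.51 and Lamb3 at 1.40. In T cells Peak1 (0.98, 0.43 to 1.56) and Sh2d2a (0.94, 0.65 to 1.23) were higher and Ppp1r21 (-1.21, -1.79 to -0.64) and Brox (-1.18, -1.80 to -0.58) lower, and in Xist-only cells 1.14, 0.68, -0.46 and -1.05. In dendritic cells Il9, a cytokine of type 2 immunity, had 534 UMIs with the peptide and 0 in both other libraries, at least 140-fold higher than with saline, but all 534 were in 1 cell. H2-Q7 was higher at 1.10 and 1.00, Tm4sf5 was at -1.38 and -0.07, and Ifitm2 at -0.77 and 0.33, the Xist-only value given second. In innate lymphoid or gamma-delta T cells Cd5 (2.31 in both readings) and Gem (1.46 and 1.81) were higher, with Ttc28 at -1.11 and -0.96 and AA467197 at -1.003 and 0.092. With the strict filter on cells Cd5 was at -0.52. Hmgb1 was close in phagocytes, at 334 and 337 CPM, and lower in mesenchymal cells at -0.27.

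Whether the peptide library lay nearer to room air was read from the genes at least 2-fold apart under hyperoxia. In phagocytes 93.6% of them went the other way, against 49.2% in simulated libraries without a difference, and in classical monocytes 94.7% against 49.4%. Both ratios use the hyperoxia saline library, so splitting its cells removes counting error but not a deviation of that library or its pups. The simulated libraries hold no such deviation, so the gap to them does not single out the peptide. With no pup in common, picking genes in Y-only cells and reading them in Xist-only cells, the shares were 56.1% and 51.3%. Within the hyperoxia saline library, Xist-only cells differed from Y-only cells in the same way. There 95.3% of such genes in phagocytes and 91.0% in classical monocytes went the other way. In that reading the Y-only cells both picked the genes and served as reference, so a deviation of those cells alone raises the share. In type 2 cells the 3 readings were 82.3%, 67.8% and 65.2%, in neutrophils 69.9%, 40.6% and 70.2%, in endothelial cells 61.4%, 55.6% and 54.9% and in mesenchymal cells 66.7%, 48.3% and 74.6%. The pups of the hyperoxia saline library differ in sex, and nothing in the labels separates sex from the single animals.

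**Figure D4:**
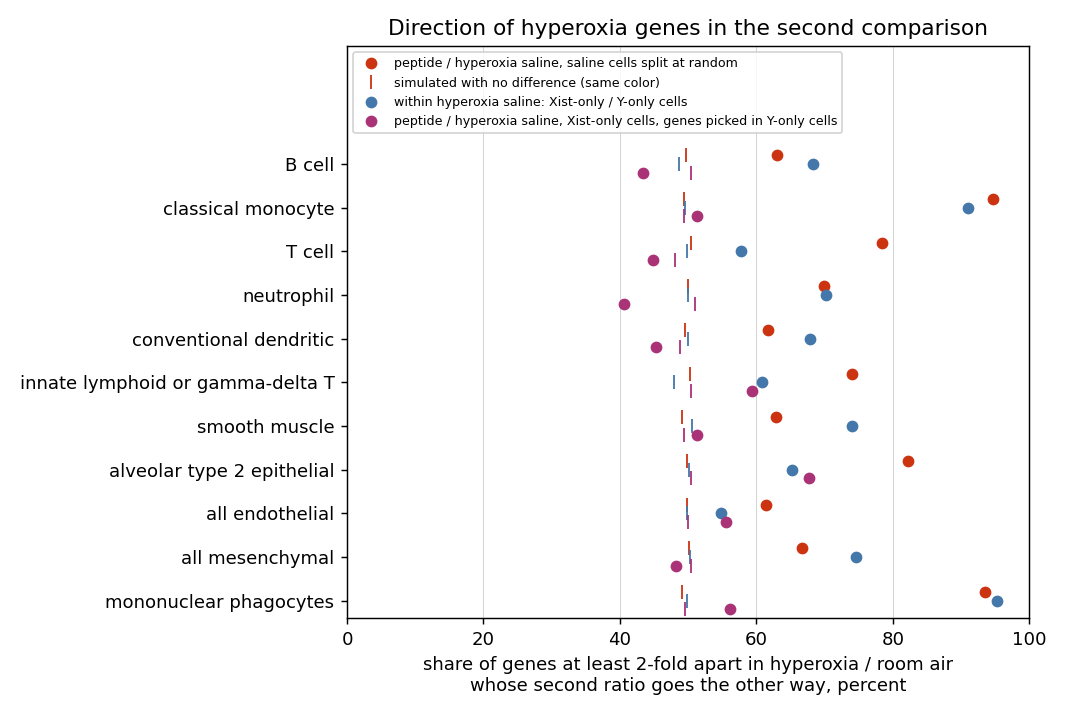
Points give, per population, the percent of genes at least 2-fold apart under hyperoxia that went the other way in 3 comparisons, and ticks give simulated libraries without a difference. Phagocytes stood at 93.6% for the peptide with the saline cells split, 56.1% with no pup in common and 95.3% within the saline library.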

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

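Thinned cells, list medians in Xist-only cells, the strict filter and all deposited barcodes were planned settings, and the other tests weighed here and the pooled populations were chosen after the results were seen. Xist and the Y-linked genes used here are in data that the deposited normalized table leaves out. Xist without Y-linked transcripts was found in 34.7% of the deposited barcodes of the hyperoxia saline library and in 86.3% of those of the peptide library, above the limit of 3 counts that its 0 barcodes in room air allow. The labels give no sex, pups were assigned at random, and each library came from 2 pups, so sex, treatment and single animals move together.

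Lower inflammation in the peptide library was the first pattern weighed: neutrophils were 2.55-fold lower than with saline and the inflammatory list of phagocytes had a median of -0.54. With cells thinned to 1500 UMIs that median was -0.67, which argues against unequal weights of deep and shallow cells as its source. Thinning reused the clusters of the unthinned data and keeps proportions by design, so it cannot decide on other effects of depth. Pups of different sex, or of different condition, may account for the phagocyte list, which had a median of 0.12 in Xist-only cells, and for neutrophils the ratio to the depth-corrected female estimate was -0.24 (-0.78 to 0.37), an interval too wide to decide. Within the hyperoxia saline library, 95.3% of the phagocyte genes that differed under hyperoxia went back toward room air in Xist-only against Y-only cells. In that reading the Y-only cells both picked the genes and served as reference, so a deviation of those cells alone raises the share. With no pup in common 56.1% went back in the peptide library, against 49.6% in simulated libraries without a difference. An effect of the peptide, of sex, or of the single female pup in the saline library stays open.

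Clusters nearly without cells under hyperoxia were the second pattern: alveolar macrophages, general capillary cells and myofibroblasts. The tables argue against sex for alveolar macrophages, with a log2 ratio of -5.59 in Y-only cells, and against the filters on cells, with -4.84 over all deposited barcodes. Cells counted in another cluster of the same lineage cannot be the whole cause in endothelial cells, since all of them together were at -1.34. They may be part of it, since unnamed cluster 17 held 84.6% of the hyperoxia endothelial cells. Which capillary class it belongs to is not settled. By mean fold it was nearest to the general capillary markers, but that measure was set aside for names. Its 10 leading genes hold Cd93 of the general capillary set and Apln of the aerocyte (Car4) capillary set. For alveolar macrophages that border stays open, as all phagocytes together were at 0.55, and a hypothesis not tested is that altered alveolar macrophages sit in the unnamed clusters. For myofibroblasts this was not tested. Of the mesenchymal cells in room air and hyperoxia saline, smooth muscle cluster 11 was 18.8% and 36.7% and cluster 19 6.21% and 32.6%. Alveolar fibroblasts were 12.0% and 23.7% and adventitial fibroblasts 12.9% and 6.96%. A loss of cells, a change of their state and a lower yield from the injured tissue may all contribute. Higher shares of neutrophils and phagocytes also lower the shares of all other classes.

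Type 2 cell lists with medians toward room air in the peptide library were the third pattern. The p53 targets had a median of -0.33 over all cells and -0.32 in Xist-only cells, which argues against the mix of sexes as the cause for that list. With the strict filter on cells, from 27 saline type 2 cells, the p53 targets stayed lower at -0.20, while the NRF2 targets at 0.36, the transitional state at 0.72 and the surfactant genes at -0.16 turned direction, as did the transitional state in Xist-only cells at 0.11. The peptide may be a cause, but 67.8% of all genes that differed under hyperoxia went back with no pup in common, against 50.4% in simulated libraries without a difference, and 65.2% did so within the saline library. With 1 library per group, the peptide and the pups cannot be told apart.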

How the results depend on the processing

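The shares within Y-only and Xist-only cells, with or without thinning, the pooled phagocyte, endothelial and mesenchymal populations and the readings with no pup in common were chosen after the results were seen; the other settings were planned. No paired analysis was possible because each group is 1 library and the labels give no pairs. Depth limits Xist-only neutrophils (29 saline cells) and the small clusters. Where no cause is named, the cause was not tested. A result turned direction if its sign changed and its main interval excluded 0. Otherwise it was kept if the new value lay within the main interval, which covers counting error only, and moved if outside. A change of sign where the main interval held 0 thus counts as kept or moved. Of 60 list medians the loose filter kept 53 and moved 5, the strict filter 24 and 32, no doublet removal 48 and 11, double the doublet rate 53 and 6, centred ratios 51 and 9, a mean over cells 48 and 12, and thinning 31 and 28, the rest turning direction (4 with the strict filter). Of 30 list medians Y-only cells kept 14 and moved 16, and Xist-only cells kept 10, moved 10 and turned 10. Of 24 share ratios resolution 0.5 kept 23, resolution 2 kept 22, all deposited barcodes 22, the loose filter 20, no doublet removal 22 and double the doublet rate 23, the rest moving, while the strict filter kept 10, moved 13 and turned 1. Of 12 share ratios Y-only cells kept 7 and moved 5, with or without thinning, and Xist-only cells kept 5, moved 4 and turned 3, or 5, 5 and 2 when thinned. Of 88 gene ratios, where measured, the loose filter kept 75 and moved 13, the strict filter kept 40, moved 40 and turned 6, no doublet removal 69, 16 and 2, double the doublet rate kept 75 and moved 12, a mean over cells 76 and 6, and thinning 49 and 39. Y-only cells kept 34 gene ratios, moved 9 and turned 1, and Xist-only cells kept 19, moved 20 and turned 5.

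With the loose filter on cells the neutrophil share was at 1.47 for hyperoxia and -0.73 for the peptide, the inflammatory list of neutrophils at -0.16 and 0.20, and the collagen list of mesenchymal cells for the peptide at 0.029. With no doublet removal the neutrophil share was at 1.39 and -0.84, the inflammatory list of neutrophils for hyperoxia at -0.10, and for the peptide collagen at 0.030, Ccl21a at 1.83 and Gstm1 at -0.46. Double the doublet rate gave collagen 0.033 and elastic fibre -0.0021 for the peptide.

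With the strict filter on cells the neutrophil share was at 3.17 and -3.47, from far fewer neutrophils, the phagocyte share for hyperoxia at 0.77 and the B cell share for the peptide at -1.08. The inflammatory list of phagocytes was at 2.25 and -0.74. For hyperoxia the dissociation list of endothelial cells was at -0.094, Retnla in monocytes at 0.63 and Cmah in innate lymphoid cells at 2.73. For the peptide Col5a3 was at -1.51 and Lamb3 at 1.40 in B cells, Cd5 at -0.52 in innate lymphoid cells and Tnfrsf12a at 0.22 in type 2 cells, where p53 targets were at -0.20, NRF2 targets at 0.36, surfactant genes at -0.16, the transitional state at 0.72 and Lyz1 at 0.36.

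In Y-only cells the neutrophil share was at 2.52, and 2.87 when thinned, where 62 of 200 room air neutrophils were left out, the phagocyte share at 0.79, the inflammatory list of phagocytes at 1.83 and Vpreb1 in B cells at most -2.41. In Xist-only cells shares were at -0.39 for neutrophils (-1.11 thinned, no test of the share, as thinning left out 292 of 439 peptide and 82 of 662 saline neutrophils), 0.069 for phagocytes (0.20 thinned), -0.46 for B cells (-0.73 thinned) and -0.037 for type 2 cells, with alveolar macrophages at 2.35 when thinned. There the list medians were 0.12 for inflammatory genes, 0.31 for metallothionein and stress and -0.11 for MHC class II in phagocytes, 0.70 for inflammatory and 0.65 for hypoxia genes in neutrophils, -0.0084 for interferon-stimulated genes in monocytes, 0.00090 for hypoxia genes in endothelial cells, 0.046 for TGF-beta response and 0.15 for metallothionein and stress in mesenchymal cells, and 0.11 for the transitional state. Saa3 was at 2.05 in phagocytes, Mt2 at 0.11 in mesenchymal cells and 0.032 in smooth muscle, Ifitm2 at 0.33 in dendritic cells and AA467197 at 0.092 in innate lymphoid cells.

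With cells thinned the inflammatory list of phagocytes was at 1.58 and -0.67, the p53 list of type 2 cells for hyperoxia at 1.56, and for the peptide collagen at 0.013 and interferon-stimulated genes at -0.022 in mesenchymal cells. For hyperoxia the inflammatory list of phagocytes was at 1.87 centred and 1.65 as a mean over cells, the p53 list of type 2 cells at 1.96 with at least 100 CPM, and the stress list of phagocytes at -0.20 with no minimum CPM. The share of genes going the other way was 90.6% in phagocytes from 1.5-fold, and with no pup in common 56.1% in phagocytes, 48.3% in mesenchymal cells, 45.3% in dendritic cells, 44.8% in T cells, 43.4% in B cells and 40.6% in neutrophils.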

Other observations

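The within-library comparisons here were chosen after the results were seen. In the hyperoxia saline library, the only one with cells of both sexes, Xist-only cells held fewer neutrophils than Y-only cells, with a log2 ratio of shares of -2.71 (-3.32 to -2.16) from 29 and 252 cells. Cluster 8, the Spp1 and Arg1 phagocytes, was at -2.19 and cluster 14 of the neutrophils at -3.28, while B cells were at 1.48 and type 2 cells at 1.014. Detection of Xist and of Y-linked transcripts depends on depth and on cell type, so these ratios are not free of it. Xist alone was found in 22.3% of peptide neutrophils against 87.0% of all kept peptide cells. Y-linked transcripts alone were found in 47% of room air neutrophils against 65.8% of all kept room air cells. Lower detection of Xist in neutrophils thus makes -2.71 overstate the difference, beyond what its interval covers. By an estimate from detection rates at matched depth, 114 of the 662 neutrophils were female and 539 male, which sum to 653.

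Dendritic cells had cell cycle genes higher under hyperoxia, 17 of 27 with 0 lower and a median of 0.81. Their cluster 35, nearest to the cycling markers, held 1 of the 180 dendritic cells in room air and 17 of the 197 under hyperoxia, so this median moves with its share. In mesenchymal cells 9 of 12 interferon-stimulated genes were higher under hyperoxia and 0 lower, with a median of 1.26 (1.02 to 1.41). That is the opposite direction to classical monocytes. Isg15 stood at 5.51 and 36.6 CPM. The mix of mesenchymal clusters differed between these libraries, with smooth muscle at 113 of 451 cells in room air and 219 of 316 under hyperoxia. In endothelial cells interferon-stimulated genes were lower in 8 of 16 cases and higher in 0. Dissociation and immediate early genes, which respond to the handling of tissue, were lower in 11 of 23 cases in type 2 cells, with a median of -0.57 (-0.67 to -0.42), and higher in 11 of 25 in endothelial cells, with a median of 0.34, and -0.094 with the strict filter on cells. Natural killer cells were 2.03%, 2.08% and 3.48% of the cells in room air, hyperoxia saline and peptide, and plasmacytoid dendritic cells were 24, 23 and 91 cells. In Xist-only cells the log2 ratio of the peptide to the saline share was 0.29 (-0.22 to 0.85) for natural killer cells. For plasmacytoid dendritic cells it was 1.36 (0.32 to 2.61). A cluster led by the cardiac genes Myl7 and Tnni3 held 2, 16 and 25 cells.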
